A study of Mus musculus with 24 samples.

How the data were processed

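RNA was sequenced from 24 libraries, 3 in each of 8 groups, made from live CD45-negative cells sorted from day 15 tumours of the LLC1 and KP mouse lung cancer lines. Per the labels' protocols, red blood cells were lysed, RNA was treated with DNase I, and stranded total RNA libraries were sequenced paired-end on a NovaSeq. The submitters' processing notes name cutadapt 2.9, Salmon 1.8.0 and DESeq2 1.34.0 and the mouse build GRCm38/mm10, without giving each tool's role. The deposited values are on a log2 scale after variance stabilisation, as judged from the tables' title and values, in 1 table of 31618 genes for the 9 LLC1 libraries and another of 36040 genes for the 15 KP libraries. The tables were normalised separately, so expression values were not compared between lines, only differences from parental tumours. All columns were used. Gene identifiers were matched to GENCODE vM21 for symbols and GRCm38 coordinates, leaving 70 LLC1 and 85 KP identifiers unmatched and tested without a symbol.

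The lowest deposited value (8.03 in LLC1, 8.17 in KP) was taken as a count of 0. Normalised counts were calculated back by inverting a stabilisation whose lower limit is that value. In every library 76.4% to 81.8% of low values then fell within 0.15 reads of a whole number of reads, against 30% by chance. The spacing gave an estimated depth of 13.3 to 34.9 M fragments in LLC1 and 13.7 to 32.7 M in KP, with 22104 to 30700 genes detected. Folds and counts in the text come from these back-calculated values and log2 differences from the deposited values, which are compressed at low counts.

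Genes were kept where the mean of at least 1 group lay 1 log2 unit or more above the lowest value, about 130.4 normalised counts in LLC1 and 144.2 in KP. This kept 10581 LLC1 genes (33.5%) and 11193 KP genes (31.1%), holding 99.1% and 99.0% of counts. Differences were fitted with limma 3.58.1 in R 4.3.3 on the deposited values with an intensity trend and all groups of a line in 1 fit. The Benjamini and Hochberg adjustment was made over kept genes per comparison, and adjusted p below 0.05 was called. There were 9 comparisons, 3 in LLC1 and 6 in KP, of which 6 were with parental tumours. The median chi-square between replicate pairs was 1.65 to 4.03 against 0.455 expected from counting alone, so counting error was not the main source of spread. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The seed was 11.

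The groups compared, the filter, the tests and 32 gene lists were fixed before the data were examined. The lists covered interferon, antigen presentation, inflammation, lineage, proliferation, metabolism and stress genes, markers of host cell types and a sex-linked check. Lists with at least 3 kept members were tested with limma camera at a preset correlation of 0.01, adjusted over 23 lists in LLC1 or 24 in KP, and again with the correlation estimated from the data. The genes named in the text followed a rule. They were the 8 highest and 8 lowest log2 differences per comparison with parental tumours (4 and 4 for the others) among called genes with a symbol that is not a predicted-gene name, a mean of 3 or more log2 units above the lowest value in at least 1 group, and all 3 values of one group above those of the other. To these were added up to 4 members of each list with the largest absolute difference and 16 IFNG pathway genes. A few genes that the rule named are not reported here. With 3 against 3 libraries no exact test can go below 0.1, so p-values rest on limma's variance model.

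The gene test was tested on simulated data for the 6 comparisons with parental tumours, with 200 genes changed by log2 steps of 0.25, 0.5 and 1. Recovery at these steps was 41.8%, 82.1% and 98.5% for chronic IFNG LLC1, 37.3%, 89.6% and 100% for relapsed LLC1, 61.2%, 97.0% and 100% for chronic IFNG KP, 56.7%, 86.6% and 100% for 1st relapse, 46.3%, 94.0% and 100% for 2nd relapse, and 41.8%, 92.5% and 98.5% for late relapse. Correlation from shared parental tumours was simulated in 200 draws.

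Alternatives fixed in advance were no filter, a stricter filter of 3 log2 units, quantile normalisation, median centring, limma without a trend, fits of 2 groups only, array weights, the replicate number as a block, leaving out each library, a threshold of 1 log2 unit, estimated correlation, the fry test and lists without members shared with the IFNG response list. Back-calculated counts with a pseudocount of 10, a satellite-like RNA covariate, and scalings and left-out libraries for all lists were added after the data were seen.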

Results

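Gene expression was compared between live CD45-negative cells sorted from day 15 tumours of 2 mouse lung cancer lines, Lewis lung carcinoma (LLC1) and KP. LLC1 tumours were parental, derived from cells kept under chronic low-level interferon gamma (IFNG), or relapsed after immune checkpoint blockade. KP tumours were parental, chronic IFNG, 1st relapse, 2nd relapse or late relapse. Every group held 3 libraries, called biological replicates by the submitters. The labels give no statement on separate animals, so p-values measure spread between these samples. LLC1 and KP values were normalised separately, so groups were tested only within their own line, and across lines only the differences from parental tumours were set side by side. Changes are given as log2 differences on the deposited scale and as folds of normalised counts, mean ± SD with n = 3. A gene was called at a limma adjusted p below 0.05, gene lists were tested with limma camera, counts adjusted over the list alone are given where they differed from those over all genes, and coordinates are on GRCm38.

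**Figure D1:**
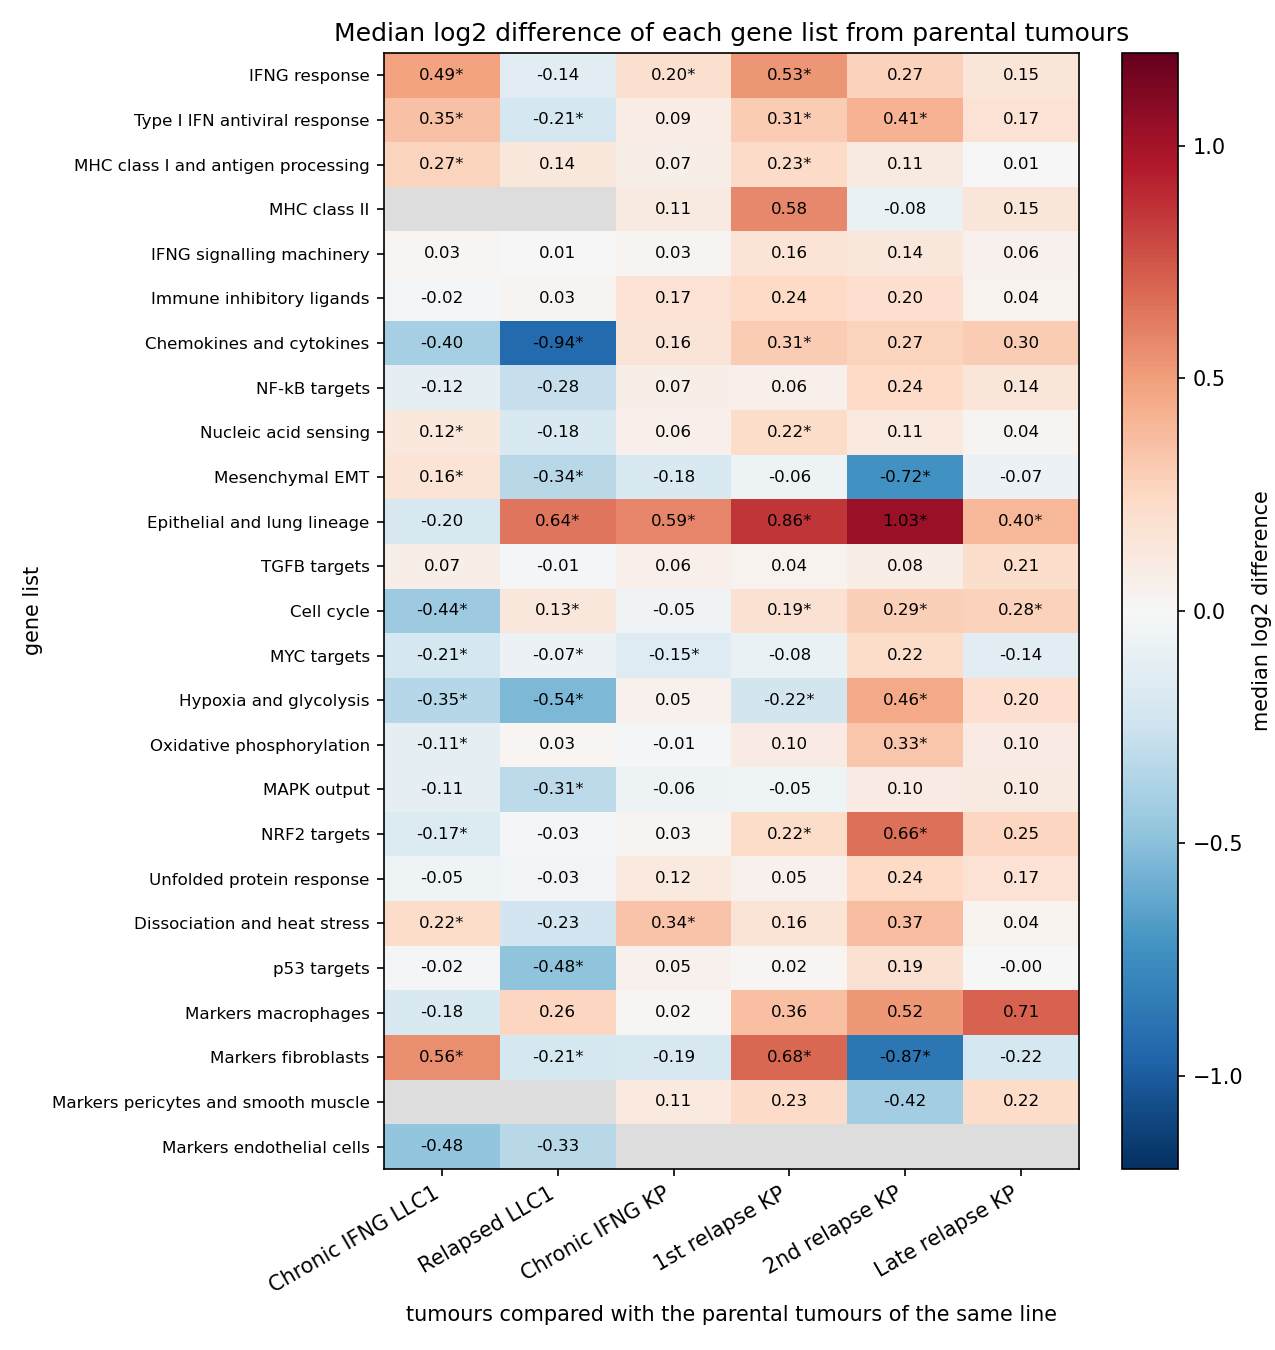
Median log2 difference of each gene list in the 6 comparisons with parental tumours. Stars mark lists with a camera adjusted p below 0.05, and grey marks lists with fewer than 3 tested members.

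Chronic IFNG LLC1 tumours had higher interferon and fibroblast genes and lower cell-cycle genes than parental tumours (n = 3 per group, preset correlation). This addressed how tumours of the chronic IFNG line differed from parental ones. The chemokine Cxcl10 rose 2.25-fold (1567 ± 603 against 697 ± 314). The cartilage matrix gene Cilp (chr9:65265180-65280605) rose 11.5-fold, from 381 ± 139 to 4373 ± 1962. The replication enzyme Top2a fell 1.77-fold, from 9260 ± 1413 to 5233 ± 443. In total 2596 genes were called, 955 higher and 1641 lower, and 47 of them (36 higher, 11 lower) differed by at least 1 log2 unit.

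Of the IFNG response genes 29 of 39 rose and 0 fell, 34 and 0 adjusted over the list alone, with a median log2 difference of 0.49 and a camera adjusted p of 4.7e-15 (adjusted p = 0.36 with an estimated correlation). The largest rises were in guanylate-binding and related GTPases that act against intracellular pathogens, Gbp4 (6.89-fold), Tgtp1 (6.75-fold), Gbp9 (4.41-fold) and Gbp2 (2950 ± 1028 against 1254 ± 92.9). Gbp and Tgtp genes have near-identical copies, so the split of reads between them is uncertain. In the type I interferon antiviral list 20 of 37 rose and 1 fell, 27 and 1 adjusted over the list alone, median 0.35, adjusted p 3.2e-11 (adjusted p = 0.411 with an estimated correlation). Rsad2, Ifit3 and Trim30a were up 3.02, 2.70 and 4.75-fold. MHC class I and antigen processing genes showed 9 higher and 0 lower of 20, 11 and 0 adjusted over the list alone, median 0.27, adjusted p 4.1e-05 (adjusted p = 0.411 with an estimated correlation). Among them the class I transactivator Nlrc5 rose from 326 ± 87.6 to 892 ± 409.6, the peptide loader Tapbp 1.57-fold and the peptide transporter Tap1 by a log2 difference of 0.46. Class I chains stayed uncalled, with log2 differences of 0.48 for H2-D1, 0.25 for B2m and 0.15 for H2-K1. Nucleic acid sensors showed 6 higher and 0 lower of 13, median 0.12, adjusted p 6.4e-04 (adjusted p = 0.315 with an estimated correlation), led by Ifi204 (2.14-fold) and the RNA sensor Ddx58 (1.59-fold). In the IFNG signalling machinery 4 of 19 rose and 1 fell, median 0.03, adjusted p 0.172 (without Chronic IFNG LLC1 replicate 1 0.0375 and a median of -0.01). Irf1 rose from 1865 ± 155 to 2809 ± 432, while Ifngr1 (-0.05), Ifngr2 (-0.09), Jak1 (0.01), Jak2 (-0.10) and the feedback inhibitor Socs1 (0.16) were not called. Cd274, which encodes the checkpoint ligand PD-L1, was not called at 309.8 ± 72.4 against 218 ± 30.1. Calls in this group leaned on single libraries. Without Parental LLC1 replicate 1 the limma adjusted p became 0.0628 for Tap1, and without Chronic IFNG LLC1 replicate 2 it became 0.11 for Cxcl10. Without Chronic IFNG LLC1 replicate 1 it reached 0.00114 for H2-D1, 0.00671 for B2m, 0.0414 for H2-K1 and 0.0273 for Cd274, and without Parental LLC1 replicate 3 it reached 0.0417 for Socs1. With the fry test the adjusted p was 0.0502 for the type I list and 0.0597 for MHC class I genes.

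Of the mesenchymal and EMT genes 13 of 28 rose and 4 fell, 14 and 4 adjusted over the list alone, median 0.16, adjusted p 1.2e-04 (adjusted p = 0.315 with an estimated correlation). Col1a2 was up 2.80-fold, Col1a1 2.79-fold, fibronectin Fn1 2.33-fold and tenascin Tnc from 12240 ± 2426 to 32738 ± 3581. Fibroblast markers moved the same way, 11 higher and 0 lower of 14, median 0.56, adjusted p 4.5e-09 (adjusted p = 0.315 with an estimated correlation), including Dpt (4738 ± 864 against 1637 ± 538), Col6a3 (2.43-fold), Postn (2.61-fold) and Dcn (1.86-fold). Their summed level was 6681 ± 1221 in counts scaled to an equal total (CPM) against 3428 ± 461 in parental tumours. Aspn (5.12-fold), Aqp1 (3.94-fold), Col4a5 (4.45-fold), Col8a1 (3.64-fold) and the growth factor Ptn (4.31-fold) were the other largest rises. The immediate-early genes Fosb (3.27-fold) and Fos (2.39-fold) led the dissociation and heat stress list, 7 higher and 1 lower of 17, median 0.22, adjusted p 0.00379 (adjusted p = 0.411 with an estimated correlation), which became 0.0964 without Parental LLC1 replicate 3 and 0.112 with the fry test.

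Proliferation genes fell. In the cell cycle list 32 of 35 fell and 0 rose, 33 and 0 adjusted over the list alone, median -0.44, adjusted p 1.7e-15 (adjusted p = 0.315 with an estimated correlation), with the mitotic genes Kif23 (2.199-fold lower), Cenpf (1.83-fold) and Bub1 (1.91-fold). MYC targets (12 of 25 fell and 0 rose, 15 and 0 adjusted over the list alone, median -0.21, adjusted p 4.2e-05, adjusted p = 0.411 with an estimated correlation) included the polyamine enzyme Odc1, 2.09-fold lower, and nucleolin Ncl, 1.54-fold lower. Hypoxia and glycolysis genes (11 of 24 fell and 0 rose, 18 and 0 adjusted over the list alone, median -0.35, adjusted p 1.8e-05, adjusted p = 0.411 with an estimated correlation) included the vasodilator peptide Adm (2.88-fold lower), Egln3 (1.98-fold) and hexokinase Hk2 (1.71-fold), and the call was lost with the fry test (0.0556). For oxidative phosphorylation 10 of 27 fell and 0 rose, 13 and 0 adjusted over the list alone, median -0.11, adjusted p 1.2e-04 (adjusted p = 0.315 with an estimated correlation), with Cyc1 at a log2 difference of -0.37. NRF2 targets (5 of 16 fell and 0 rose) had a median of -0.17 and an adjusted p of 0.00245 (adjusted p = 0.411 with an estimated correlation), with Akr1b8 1.30-fold lower. Xist, the X-inactivation RNA (chrX:103460366-103483254), fell 18.1-fold from 2843 ± 562 to 157 ± 13.5 and was the only tested gene of the sex-linked host check in LLC1. Retinoid-binding Crabp1 (10.4-fold), the stromelysin Mmp3 (12524 ± 899 against 46083 ± 7283), Ier3 (2.18-fold), Fam110c (2.54-fold) and Emb (2.46-fold) were the other largest falls.

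The other lists in this LLC1 comparison were not called. Chemokines and cytokines (3 higher and 5 lower of 14, 3 and 8 adjusted over the list alone, median -0.40, adjusted p 0.141) held a rise of Cxcl10 beside falls of Il33 (-0.83) and Ccl11 (-0.80). NF-kB targets (1 higher and 6 lower of 18, 1 and 7 adjusted over the list alone) had a median of -0.12 and an adjusted p of 0.0594, MAPK output (2 higher and 5 lower of 19, 2 and 7 adjusted over the list alone) -0.11 and 0.0609 with Spry4 at -0.43, and TGFB targets (4 higher and 0 lower of 16) 0.07 and 0.0717 with Tgfb3 up 2.46-fold. These 4 lists reached 0.00299, 6.4e-04 and 0.0202 without Parental LLC1 replicate 3 and 0.014 without Parental LLC1 replicate 1. With all libraries NF-kB targets and MAPK output reached 0.0439 and 0.0439 with median centring, and NF-kB and TGFB targets 0.0491 and 0.0212 under the stricter filter. Epithelial and lung lineage genes (0 higher and 1 lower of 4, 0 and 2 adjusted over the list alone, adjusted p 0.234) and the unfolded protein response (2 higher and 3 lower of 19, adjusted p 0.754) also stayed uncalled. For inhibitory ligands (1 higher and 3 lower of 13) the median was -0.02 while the test pointed up at 0.824, and for p53 targets (3 higher and 2 lower of 18) the median was -0.02 and the mean 0.02, adjusted p 0.645. Among host markers the endothelial list (1 higher and 2 lower of 3, median -0.48, adjusted p 0.276) had Flt1 2.64-fold lower and Eng 1.45-fold higher, and macrophage markers (0 higher and 1 lower of 3, 0 and 2 adjusted over the list alone) summed to 26.2 ± 1.65 against 25.9 ± 2.87 CPM. Mmp9 of the neutrophil list rose 2.25-fold, Arhgdib of the leukocyte list fell 2.13-fold and Fabp4 of the skin, muscle and fat list fell 3.56-fold. Pdgfrb of the pericyte list (0.06), Bpgm (0.14) and Hbb-bs (0.04) of the erythroid list and Ifi30 of the MHC class II list (0.10) were not called. The T and NK cell and B cell lists had no tested member in either line. The called genes numbered 1554 without Parental LLC1 replicate 1 against 2596 with all libraries.

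Relapsed LLC1 tumours lost p53 target and hypoxia expression against parental LLC1 tumours (n = 3 per group), while Cxcl10 fell and class I heavy chain genes rose, which addressed whether tumours relapsed after checkpoint blockade keep interferon-driven genes. The cell-cycle inhibitor Cdkn1a fell 7.71-fold, from 2561 ± 319 to 332 ± 49.5. The class I heavy chain H2-K1 rose 1.87-fold, from 2019 ± 74.2 to 3784 ± 531. The macrophage elastase gene Mmp12 (chr9:7344381-7369499) fell 25.2-fold to 722 ± 185. Of 4809 called genes 2742 were higher and 2067 lower, with 44 higher and 106 lower by at least 1 log2 unit. The majority turned with median centring (2362 higher and 2458 lower) and without a filter (2816 and 3106).

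Of the p53 targets 16 of 18 fell and 0 rose, median -0.48, and this list kept its call with a preset (camera adjusted p 9.3e-10) and an estimated correlation (adjusted p = 0.0233 with an estimated correlation). Cyclin G1 gene Ccng1 fell 4.94-fold (965 ± 150.3 against 4769 ± 520.2), Trp53inp1 3.79-fold and the p53 ubiquitin ligase Mdm2 2.13-fold. Hypoxia and glycolysis genes (20 of 24 fell and 1 rose, 21 and 1 adjusted over the list alone) had a median of -0.54, adjusted p 9.2e-08 (adjusted p = 0.654 with an estimated correlation), with the oxidoreductase Ero1l (2.88-fold lower), the glucose transporter Slc2a1 (2.26-fold), Vegfa (2.33-fold) and Adm (2.39-fold). In the MAPK output list 10 of 19 fell and 3 rose, 12 and 3 adjusted over the list alone, median -0.31, adjusted p 0.00372 (adjusted p = 0.3 with an estimated correlation). Ccnd1 and Dusp4 were down by log2 differences of -0.58 and -0.56. With the stricter filter the adjusted p of the list was 0.265.

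Interferon genes split. Of the IFNG response genes 5 of 39 rose and 10 fell, 5 and 8 adjusted over the list alone, median -0.14, adjusted p 0.297, with the inflammatory caspases Casp4 (5.03-fold) and Casp1 (4.003-fold) up and Cxcl10 (176 ± 28.9 against 697 ± 314) and Iigp1 (3.30-fold) down. The type I interferon list (11 of 37 fell and 4 rose, 8 and 4 adjusted over the list alone) was lower, median -0.21, adjusted p 0.00439 (adjusted p = 0.737 with an estimated correlation). Ifit3 was down 3.91-fold, Zbp1 down 2.83-fold and Ifit2 up 2.00-fold. In MHC class I and antigen processing 6 of 20 rose and 3 fell, median 0.14, adjusted p 0.47 (0.0443 without a filter). H2-D1 was up 1.60-fold, while B2m (0.13), Tap1 (0.06) and Nlrc5 (0.42) were not called. Ifi30, the only tested MHC class II gene in LLC1, rose 1.51-fold. For the IFNG signalling machinery (2 higher and 4 lower of 19) the median was 0.01 and the mean -0.08, adjusted p 0.47. Irf1 fell by a log2 difference of -0.32, Ifngr2 by -0.19, and Ifngr1 (0.22) and Jak1 (0.29) rose. Jak2 (-0.12) and Socs1 (0.11) were not called, and without Parental LLC1 replicate 3 the limma adjusted p of Jak2 was 0.0402. Cd274 fell to 136 ± 21.4 from 218 ± 30.1, with a limma adjusted p of 0.0829 without Relapsed LLC1 replicate 3. Inhibitory ligands (3 higher and 4 lower of 13) had a median of 0.03 with a test pointing down at 0.851, the ectoenzymes Nt5e (5.95-fold) and Entpd1 (3.08-fold) being higher. Nucleic acid sensors (4 higher and 5 lower of 13, 4 and 6 adjusted over the list alone) had a median of -0.18, adjusted p 0.256. In a fit chosen after the data were seen, with the satellite-like RNA level as a covariate, the IFNG response median turned to 0.37 (adjusted p 9.3e-08) and the type I median to 0.33, and the MHC class I median was 0.57 (5.7e-05). In that fit Irf1 (0.05), Cd274 (0.08), Cxcl10 (0.31), Iigp1 (0.26) and Ifit3 (0.21) also turned. All relapsed tumours lay below all others in that RNA (706 ± 220.1 counts against 34527 ± 24355 in parental tumours), so group and covariate could hardly be separated.

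Chemokine and mesenchymal lists fell. Chemokines and cytokines (11 of 14 fell and 1 rose, 11 and 2 adjusted over the list alone) had a median of -0.94, adjusted p 5.0e-05 (adjusted p = 0.509 with an estimated correlation). The alarmin Il33 was down 14.5-fold (1020 ± 220.3 against 14817 ± 3346), Ccl11 down 36.9-fold, Lif 8.55-fold and Ccl2 2.53-fold. Mesenchymal genes (17 of 28 fell and 2 rose, 17 and 3 adjusted over the list alone) had a median of -0.34, adjusted p 1.4e-04 (adjusted p = 0.3 with an estimated correlation). Tnc was down 6.72-fold, Col1a2 2.59-fold, Itgb3 2.70-fold and Col1a1 1.97-fold. Fibroblast markers (6 of 14 fell and 0 rose) had a median of -0.21, adjusted p 0.035 (adjusted p = 0.69 with an estimated correlation). The fibroblast call was lost with the stricter filter (0.563), no filter (0.0702), the fry test (0.059), quantile normalisation (0.324), median centring (0.0534) and without Parental LLC1 replicate 3 (0.08). Epithelial genes rose, 3 higher and 0 lower of 4, median 0.64, adjusted p 0.00828 (adjusted p = 0.3 with an estimated correlation). The tight-junction gene Ocln was up 5.66-fold, Hopx 2.73-fold and Krt18 1.40-fold. Without a filter the epithelial median turned to -0.04 and the call was lost (0.481). Cell cycle genes (15 higher and 2 lower of 35) had a median of 0.13, adjusted p 0.0324 (adjusted p = 0.737 with an estimated correlation). Ccna2 was up 1.85-fold and Kif11 1.69-fold. The cell cycle call was lost without Parental LLC1 replicate 3 (0.0736), with array weights (0.0507) and with the fry test (0.113). MYC targets (3 higher and 10 lower of 25, median -0.07, adjusted p 0.0401, adjusted p = 0.737 with an estimated correlation) lost their call under several other settings, reaching 0.154 without a filter, 0.126 with the stricter filter, 0.164 with the fry test, 0.115 with quantile normalisation, 0.0534 with median centring, 0.0713 with array weights and 0.101 without Parental LLC1 replicate 1, and the satellite-like RNA as covariate turned their median to 0.04 (0.615). The type I interferon call was lost with the stricter filter (0.595), without a filter (0.0702) and with the fry test (0.245).

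The largest rises were in Aspn (4457 ± 632 against 675 ± 263, 6.602-fold), the calcium-binding S100a4 (27233 ± 667 against 7518 ± 959), Col8a1 (2.77-fold), Igfbp6 (2.74-fold) and Fosb (3.15-fold), and in the near-identical copies Hist2h2aa1 (3.77-fold), Hist2h2aa2 (2.41-fold) and Rnu3a (2.58-fold). The largest falls were in Efemp1 (80.2-fold), Myh10 (49.0-fold), Mmp3 (6.20-fold) and the imprinted genes Grb10 (46.4 ± 8.98 against 2085 ± 129.9, 44.9-fold) and H19 (99.9 ± 58.2 against 2793 ± 692, 27.9-fold). Xist fell 13.8-fold. Host markers were mixed, as macrophage markers (2 higher and 1 lower of 3, adjusted p 0.409) summed to 45.9 ± 12.02 against 25.9 ± 2.87 CPM with Lyz2 up 7.51-fold, while haemoglobin Hbb-bs stood at 214 ± 195 against 6.91 ± 0.854 in the erythroid list (2 higher and 0 lower of 2). Endothelial markers (0 higher and 2 lower of 3, adjusted p 0.256) had Eng and Flt1 lower by -0.33 and -0.33, Pdgfrb rose 1.79-fold, and Arhgdib, Mmp9 and Fabp4 fell 1.73, 3.64 and 6.49-fold. NF-kB targets (3 higher and 9 lower of 18, median -0.28, adjusted p 0.0679) were not called with all libraries and reached 0.00398 without Parental LLC1 replicate 3. TGFB targets (4 higher and 6 lower of 16, adjusted p 0.4), oxidative phosphorylation (9 higher and 3 lower of 27, adjusted p 0.442), NRF2 targets (3 higher and 5 lower of 16, 4 and 5 adjusted over the list alone, adjusted p 0.4) and the unfolded protein response (4 higher and 4 lower of 19, adjusted p 0.61) were not called. Among NRF2 targets Hmox1 fell 4.48-fold, Slc7a11 fell 6.61-fold and Gsta4 rose 3.88-fold. Dissociation and heat stress genes (6 higher and 4 lower of 17, 6 and 6 adjusted over the list alone, adjusted p 0.678) had a median of -0.23 and a mean of 0.04.

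Relapsed LLC1 tumours had lower interferon and mesenchymal genes and higher cell-cycle genes than chronic IFNG ones (n = 3 per group, preset correlation). Cxcl10 fell 8.93-fold and Irf1 2.01-fold. In total 5503 genes were called, 3337 higher and 2166 lower (60.6% higher). Median centring gave 2701 higher and 2776 lower (49.3%) and no filter 3555 and 4164. Of the 5503 genes 68 were higher and 154 lower by at least 1 log2 unit.

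IFNG response genes fell, as 27 of 39 fell and 4 rose, 28 and 4 adjusted over the list alone, median -0.48, adjusted p 7.6e-08 (adjusted p = 0.379 with an estimated correlation). Iigp1 was down 8.67-fold. Type I interferon genes (29 of 37 fell and 0 rose, median -0.57, adjusted p 6.2e-10, adjusted p = 0.379 with an estimated correlation) had Ifit3 down 10.6-fold and Rsad2 5.62-fold. Nucleic acid sensors (8 of 13 fell and 1 rose, median -0.26, adjusted p 0.00154, adjusted p = 0.284 with an estimated correlation) had Ifi204 down 5.70-fold, and MHC class I genes (7 of 20 fell and 2 rose) had a median of -0.16, adjusted p 0.0237 (adjusted p = 0.632 with an estimated correlation). H2-K1 rose 1.57-fold, with a limma adjusted p of 0.0834 without Relapsed LLC1 replicate 1, and Tap1 fell by -0.40, 0.0587 without Relapsed LLC1 replicate 3. Cd274 fell 2.28-fold. Chemokines (8 of 14 fell and 0 rose, median -0.56, adjusted p 9.9e-05, adjusted p = 0.379 with an estimated correlation) had Il33 down 7.79-fold and Ccl11 16.4-fold. In the p53 list 13 of 18 fell and 0 rose, median -0.52, adjusted p 1.2e-08 (adjusted p = 0.0372 with an estimated correlation). Ccng1, Cdkn1a and Eda2r were down 4.63, 6.05 and 4.46-fold. Mesenchymal genes (21 of 28 fell and 3 rose, median -0.55, adjusted p 8.8e-08, adjusted p = 0.0935 with an estimated correlation) had Tnc down 18.0-fold and Col1a2 7.27-fold. Fibroblast markers (13 of 14 fell and 0 rose, median -0.83, adjusted p 8.2e-08, adjusted p = 0.189 with an estimated correlation) included Postn, down 4.64-fold. TGFB targets (5 of 16 fell and 1 rose, adjusted p 0.0295, adjusted p = 0.379 with an estimated correlation) and hypoxia genes (9 of 24 fell and 2 rose, adjusted p 0.0194, adjusted p = 0.715 with an estimated correlation) were lower with medians of -0.15 and -0.11, Tgfbi falling 2.67-fold and P4ha2 2.50-fold. Cell cycle genes (31 of 35 rose and 1 fell, 33 and 1 adjusted over the list alone, median 0.63, adjusted p 6.2e-10, adjusted p = 0.379 with an estimated correlation) had Kif23 up 3.38-fold and Ccna2 2.92-fold. Oxidative phosphorylation (18 of 27 rose and 1 fell, median 0.20, adjusted p 0.0018, adjusted p = 0.379 with an estimated correlation) and epithelial genes (4 of 4 rose and 0 fell, median 0.70, adjusted p 0.00405, adjusted p = 0.267 with an estimated correlation) were higher. Ndufb8 was up 1.68-fold and Ocln 9.61-fold. The largest single changes were rises of Bc1 (4.44-fold), S100a4 (3.73-fold), Nptx1 (3.43-fold) and Lama5 (3.01-fold) and falls of H19 (50.5-fold), Mmp12 (13.1-fold) and Enpp2 (10.9-fold). With the satellite-like RNA as covariate the adjusted p was 0.463 for the IFNG response (median -0.16), 0.365 for type I genes (median -0.06) and 0.18 for sensors, and the MHC class I and hypoxia medians turned to 0.10 and 0.03. The stricter filter gave 0.0854 for type I genes, 0.074 for MHC class I, 0.0671 for TGFB targets and 0.0602 for oxidative phosphorylation (medians no smaller in the last 3), and quantile normalisation gave 0.0541 for MHC class I and 0.0541 for hypoxia genes. No filter gave 0.0718 for MHC class I, 0.282 for TGFB targets and 0.131 for hypoxia genes, and turned the epithelial median to -0.02 (0.192). The fry test gave 0.147 for MHC class I and 0.236 for hypoxia genes, and MHC class I genes without those shared with the IFNG response list gave 0.278. Without Chronic IFNG LLC1 replicate 3 the MHC class I adjusted p was 0.167, without Chronic IFNG LLC1 replicate 1 that of TGFB targets 0.0606, and without Relapsed LLC1 replicate 1 that of hypoxia 0.1.

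**Figure D2:**
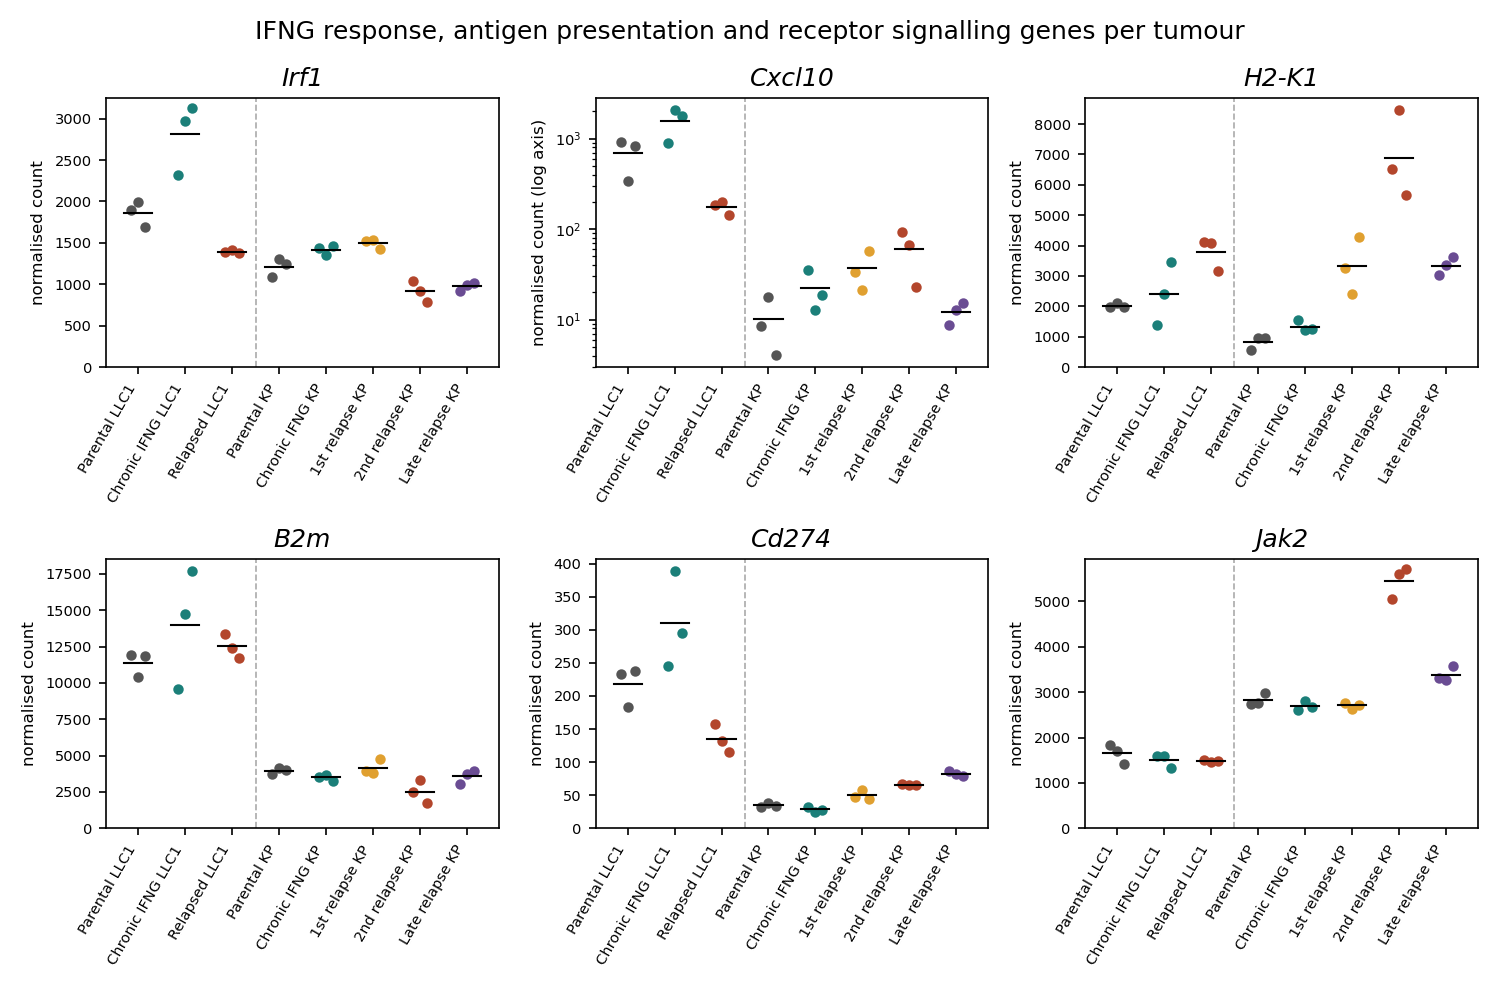
Normalised counts of single genes in each group, with dots for the 3 tumours and lines for means. The dashed line separates LLC1 from KP, which were normalised apart, and the Cxcl10 axis is logarithmic.

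In KP tumours derived under chronic IFNG, epithelial genes were much higher than in parental KP tumours (n = 3 per group), and the interferon response was raised in part, which addressed the same question as in LLC1. The mucosal glycoprotein gene Dmbt1 (chr7:131032053-131121630) rose 7.09-fold, from 9045 ± 1903 to 64146 ± 17285, and the epithelial adhesion gene Epcam 5.72-fold (4336 ± 1205 against 758 ± 142). Of 2438 called genes 1431 were higher and 1007 lower (58.7% higher), with 128 higher and 3 lower by at least 1 log2 unit. Quantile normalisation gave 1262 higher and 1386 lower (47.7%), median centring 1291 and 1508 (46.1%) and the stricter filter 410 and 562 (42.2%).

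Epithelial and lung lineage genes changed most, 13 higher and 1 lower of 19, 14 and 1 adjusted over the list alone, median 0.59, adjusted p 1.4e-09 (adjusted p = 0.547 with an estimated correlation). Mucin Muc1 was up 7.62-fold (2595 ± 744 against 341 ± 143), Krt7 4.08-fold and the transcription factor Elf3 6.61-fold. The gut peptides Tff1 (15.3-fold) and Tff2 (15.1-fold), Lgals4 (7.69-fold), Ctse (6.68-fold) and Gsta4 (7.15-fold) were the other largest rises. For the IFNG response 11 of 29 rose and 1 fell, 13 and 1 adjusted over the list alone, median 0.20, adjusted p 0.00137 (adjusted p = 0.672 with an estimated correlation). The adhesion receptor Vcam1 was up 1.86-fold, Casp1 up 8.60-fold and Upp1 down 1.71-fold. With the stricter filter the adjusted p of the list was 0.577. The receptor chains Ifngr1 and Ifngr2 rose by log2 differences of 0.33 and 0.32, Ifngr2 with a limma adjusted p of 0.139 without Chronic IFNG KP replicate 1. In the machinery list 2 of 17 rose and 0 fell, adjusted p 0.415, Jak1 (-0.06), Jak2 (-0.06) and Irf1 (0.17) being uncalled. In MHC class I and antigen processing 0 of 18 rose and 0 fell, median 0.07, adjusted p 0.591, with H2-K1 at 1336 ± 176 against 826 ± 227, H2-D1 at a log2 difference of 0.22, Tap1 at 0.25 and B2m at -0.15. MYC targets fell, 0 higher and 6 lower of 25, 0 and 13 adjusted over the list alone, median -0.15, adjusted p 4.0e-04 (adjusted p = 0.672 with an estimated correlation). Ncl was down 1.35-fold. Dissociation genes (3 higher and 0 lower of 19, 5 and 0 adjusted over the list alone, median 0.34, adjusted p 0.0174, adjusted p = 0.672 with an estimated correlation) included Btg2, up 1.81-fold, and lost their call without Chronic IFNG KP replicate 2 (0.108) and with the fry test (0.0883). The largest falls were in neuronal Map2 (3.18-fold), the ion channel Piezo2 (2.66-fold), Chst11 (2.34-fold), Tgfbi (1.89-fold), Wnt5a (2.05-fold), Dkk2 (1.97-fold), Nrep (1.76-fold) and Lgr6 (1.76-fold).

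Lists near the threshold in chronic IFNG KP were the type I interferon list (6 higher and 0 lower of 20, adjusted p 0.0657, Lgals3bp 1.75-fold), inhibitory ligands (6 higher and 2 lower of 13, 7 and 2 adjusted over the list alone, adjusted p 0.0657, Lgals9 4.54-fold and Ceacam1 3.60-fold), chemokines (5 higher and 0 lower of 12, 6 and 0 adjusted over the list alone, adjusted p 0.0646, Cxcl5 8.05-fold, Il18 3.45-fold) and mesenchymal genes (2 higher and 9 lower of 28, 2 and 10 adjusted over the list alone, adjusted p 0.0657, Sparc 1.57-fold lower). NF-kB targets (5 higher and 0 lower of 18, 8 and 2 adjusted over the list alone, adjusted p 0.0766, Nfkbiz 1.68-fold), the cell cycle (0 higher and 4 lower of 35, adjusted p 0.0735, E2f1 1.69-fold lower) and NRF2 targets (5 higher and 0 lower of 17, median 0.03, mean 0.31, adjusted p 0.0657) were close too. Each of these 7 passed 0.05 without 1 library. Without Chronic IFNG KP replicate 3 ligands reached 0.0358, chemokines 0.0122 and NF-kB targets 0.0358, without its replicate 2 mesenchymal genes reached 0.0221 and NRF2 targets 0.0304, and without Parental KP replicates 2 and 3 type I genes and the cell cycle reached 0.0356 and 0.00836. With all libraries type I genes, ligands, chemokines, mesenchymal genes, NRF2 targets and the unfolded protein response passed it with array weights, and without a filter these, NF-kB targets, p53 targets and the machinery did. MHC class II (1 higher and 0 lower of 3, adjusted p 0.238), nucleic acid sensors (2 higher and 1 lower of 11, 4 and 1 adjusted over the list alone, adjusted p 0.326, Tlr3 4.44-fold), TGFB targets (5 higher and 7 lower of 20, 6 and 7 adjusted over the list alone, adjusted p 0.848) and hypoxia genes (4 higher and 2 lower of 24, 5 and 3 adjusted over the list alone, adjusted p 0.506) were not called. Neither were oxidative phosphorylation (0 higher and 1 lower of 27, 0 and 0 adjusted over the list alone, adjusted p 0.634), MAPK output (4 higher and 3 lower of 20, 4 and 6 adjusted over the list alone, adjusted p 0.622), the unfolded protein response (4 higher and 0 lower of 20, 6 and 0 adjusted over the list alone, adjusted p 0.0735, 0.0224 with quantile normalisation) and p53 targets (5 higher and 1 lower of 18, 6 and 1 adjusted over the list alone, adjusted p 0.163). Fibroblast (0 higher and 0 lower of 13, adjusted p 0.437), macrophage (1 higher and 0 lower of 4, adjusted p 0.459) and pericyte (0 higher and 0 lower of 3, adjusted p 0.848) markers were not called. Cd53 of the leukocyte list fell 1.68-fold and the endothelial gene Flt1 fell 1.32-fold, Cidec of the skin, muscle and fat list stood at 32.6 ± 7.97 against 5.89 ± 5.28, and Xist (0.03) and Bpgm (0.12) were not called. Without Chronic IFNG KP replicate 1 the called genes numbered 1583.

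1st relapse KP tumours were higher in interferon, class I, epithelial and fibroblast genes than parental KP tumours (n = 3 per group). H2-K1 rose 4.03-fold, from 826 ± 227 to 3328 ± 941. The lipid carrier gene Apob (chr12:7977648-8016835) rose 48.1-fold, from 193 ± 80.8 to 9282 ± 1161, and the matrix proteoglycan gene Bgn (chrX:73483602-73495933) fell 10.8-fold, from 14653 ± 1282 to 1361 ± 326. The comparison addressed how KP tumours relapsed after checkpoint blockade differed from parental tumours. Of 5697 called genes 2846 were higher and 2851 lower, with 346 higher and 48 lower by at least 1 log2 unit. Quantile normalisation gave 2407 higher and 3597 lower (40.1%), median centring 2406 and 3537 (40.5%) and the stricter filter 676 and 1325 (33.8%).

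Of the IFNG response genes 22 of 29 rose and 1 fell, median 0.53, adjusted p 9.7e-06 (adjusted p = 0.524 with an estimated correlation). Parp14 was up 3.43-fold and Vcam1 1.97-fold. The stricter filter gave the list an adjusted p of 0.366. Type I interferon genes (12 of 20 rose and 0 fell, median 0.31, adjusted p 9.6e-04, adjusted p = 0.524 with an estimated correlation) had the RNA sensor Ifih1 up 4.08-fold and Lgals3bp 1.98-fold. MHC class I and antigen processing genes (13 of 18 rose and 0 fell, median 0.23, adjusted p 0.00529, adjusted p = 0.563 with an estimated correlation) had Tap1 up from 47.3 ± 21.7 to 277 ± 115, H2-D1 1.795-fold and B2m uncalled at a log2 difference of 0.06. MHC class II genes (3 of 3 rose and 0 fell) had a median of 0.58 and an adjusted p of 0.0795, 0.0492 without Parental KP replicate 2. H2-DMb1 was up 7.57-fold. In the machinery 7 of 17 rose and 1 fell, adjusted p 0.126. Ifngr2 and Ifngr1 were up 2.07 and 1.66-fold, Irf1 up by 0.23 with a limma adjusted p of 0.054 without Parental KP replicate 1, and Jak1 (-0.00) and Jak2 (-0.05) uncalled. Nucleic acid sensors (6 of 11 rose and 0 fell, median 0.22, adjusted p 0.0141, adjusted p = 0.524 with an estimated correlation) had Tlr3 up 7.31-fold, and chemokines (6 of 12 rose and 1 fell, 8 and 1 adjusted over the list alone, median 0.31, adjusted p 0.0141, adjusted p = 0.524 with an estimated correlation) had Cx3cl1 up 3.18-fold and Cxcl16 3.11-fold. Inhibitory ligands (7 higher and 3 lower of 13, 8 and 3 adjusted over the list alone, adjusted p 0.114) had Lgals9 up 7.06-fold and were not called as a list.

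Epithelial genes rose, 14 higher and 1 lower of 19, median 0.86, adjusted p 2.5e-06 (adjusted p = 0.524 with an estimated correlation). Epcam was up 9.72-fold, Muc1 11.5-fold and the hepatic and gut factor Hnf4a 8.23-fold. The secretory genes Dmbt1 (114951 ± 12694, 12.7-fold), Pigr (81.3-fold), Agr2 (42.9-fold), Lgals4 (11.1-fold), Ctse (7781 ± 393 against 707 ± 234) and Tff2 (15.2-fold) were among the largest rises. Fibroblast markers rose as well, 9 higher and 0 lower of 13, 10 and 0 adjusted over the list alone, median 0.68, adjusted p 0.0141 (adjusted p = 0.64 with an estimated correlation). Postn was up 6.75-fold, Pdgfra 4.09-fold and Dcn 2.61-fold. The markers summed to 1044 ± 136 against 576 ± 66.9 CPM, and the adjusted p was 0.0826 with the stricter filter (median no smaller). Mesenchymal genes split, 13 higher and 9 lower of 28, 13 and 11 adjusted over the list alone, with a median of -0.06, a mean of 0.30 and an adjusted p of 0.986, as collagens Col1a2 (5.49-fold), Col1a1 (4.90-fold) and Col3a1 (3.46-fold) and the cross-linker Lox (7.92-fold) rose while Tgfbi fell 2.68-fold. Cell cycle genes (21 of 35 rose and 2 fell, 24 and 3 adjusted over the list alone, median 0.19, adjusted p 0.00969, adjusted p = 0.64 with an estimated correlation) had Kif23 up 1.60-fold. NRF2 targets (9 of 17 rose and 2 fell, median 0.22, adjusted p 0.0278, adjusted p = 0.563 with an estimated correlation) had Cbr3 up 12.2-fold. Hypoxia genes fell, 2 higher and 13 lower of 24, median -0.22, adjusted p 0.0141 (adjusted p = 0.64 with an estimated correlation). Ndrg1 was down 1.97-fold. The NRF2 and hypoxia calls were lost without Parental KP replicate 3 (0.0545 and 0.0566), the NRF2 call with the satellite-like RNA as covariate (0.0517) and the hypoxia call with quantile normalisation (0.224).

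The largest falls in 1st relapse KP were in the small nucleolar Rnu3b1 (6.72-fold) and its near-identical copy Rnu3a (9.99-fold), Nrep (3.49-fold), the clock gene Arntl2 (3.71-fold), Nrg1 (4.27-fold), Cd53 (3.94-fold) and prostaglandin synthase Ptgs2 (2.94-fold). Xist fell by -0.42. MAPK output (6 higher and 7 lower of 20, adjusted p 0.563), NF-kB targets (7 higher and 4 lower of 18, adjusted p 0.465), TGFB targets (9 higher and 7 lower of 20, adjusted p 0.356), MYC targets (0 higher and 8 lower of 25, 0 and 7 adjusted over the list alone, adjusted p 0.0944) and oxidative phosphorylation (11 higher and 2 lower of 27, 10 and 2 adjusted over the list alone, adjusted p 0.116) were not called. The unfolded protein response (7 higher and 1 lower of 20, adjusted p 0.138), dissociation genes (4 higher and 4 lower of 19, adjusted p 0.611) and p53 targets (6 higher and 3 lower of 18, adjusted p 0.28) were not called either. Macrophage (2 higher and 0 lower of 4, 3 and 0 adjusted over the list alone, adjusted p 0.152) and pericyte (2 higher and 0 lower of 3, adjusted p 0.563) lists stayed uncalled. Krt14 and Cidec of the skin, muscle and fat list rose 2.29 and 8.10-fold, while Flt1 (0.11) and Bpgm (0.09) were not called.

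2nd relapse KP tumours had lower fibroblast markers and higher hypoxia and antiviral genes than parental KP tumours (n = 3 per group, preset correlation). H2-K1 rose 8.33-fold to 6878 ± 1438 and H2-D1 2.48-fold, while B2m, the light chain shared by class I molecules, fell from 3948 ± 222 to 2518 ± 793. The matrix gene Sparc (chr11:55394500-55423183) fell 45.3-fold, from 17613 ± 570.1 to 389 ± 39.3, and the galectin Lgals2 (chr15:78850860-78855529) rose 597-fold, from 39.8 ± 3.11 to 23745 ± 2624. The comparison addressed how tumours labelled 2nd relapse differed from parental tumours. Of 7367 called genes 4117 were higher and 3250 lower, with 476 higher and 277 lower by at least 1 log2 unit. The majority turned with quantile normalisation (3375 higher and 3797 lower) and median centring (3604 and 3795).

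Fibroblast markers all fell, 0 higher and 13 lower of 13, median -0.87, adjusted p 0.00313 (adjusted p = 0.802 with an estimated correlation). Dcn was down from 705 ± 182 to 42.2 ± 14.1 and Col6a3 4.18-fold, and the markers summed to 161 ± 17.6 CPM. Mesenchymal genes (19 of 28 fell and 3 rose, median -0.72, adjusted p 4.5e-04, adjusted p = 0.802 with an estimated correlation) had Tnc down 35.9-fold, Tgfbi 10.6-fold and Col3a1 10.7-fold. Epithelial genes (14 of 19 rose and 2 fell, median 1.03, adjusted p 0.00313, adjusted p = 0.802 with an estimated correlation) had Hnf4a up 11.4-fold, Krt7 5.04-fold and the junction gene Cdh1 4.33-fold. Type I interferon genes (14 of 20 rose and 2 fell, median 0.41, adjusted p 0.0167, adjusted p = 0.802 with an estimated correlation) had Oasl1 up 5.55-fold, Bst2 4.62-fold and Ifit3 19.9-fold. Among IFNG response genes 15 of 29 rose and 4 fell, median 0.27, adjusted p 0.145, which was 0.0408 without 2nd relapse KP replicate 3. Ifi47 was up 4.36-fold and Apol9b, which has a near-identical copy, 13.6-fold. In the machinery 7 of 17 rose and 4 fell, adjusted p 0.606. Jak2 was up from 2822 ± 131 to 5451 ± 354, Ifngr1 1.40-fold, Ifngr2 1.78-fold, Irf1 down by -0.28 and Jak1 uncalled (0.09). MHC class I genes (8 higher and 2 lower of 18, adjusted p 0.59) included Tap1, up by 0.38 with a limma adjusted p of 0.198 without 2nd relapse KP replicate 2, and Cd74 of the MHC class II list (1 higher and 1 lower of 3, median -0.08, adjusted p 0.8) fell 6.21-fold.

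Hypoxia and glycolysis genes rose in 2nd relapse KP, 16 higher and 1 lower of 24, median 0.46, adjusted p 0.0069 (adjusted p = 0.802 with an estimated correlation). Ndrg1 was up 2.95-fold, Slc2a1 2.51-fold, Ero1l 2.35-fold and Adm 3.31-fold. Cell cycle genes (26 of 35 rose and 3 fell, median 0.29, adjusted p 0.00819, adjusted p = 0.802 with an estimated correlation) had Rrm2 up 3.71-fold, oxidative phosphorylation (20 of 27 rose and 3 fell, median 0.33, adjusted p 0.0167, adjusted p = 0.802 with an estimated correlation) had Cox6c up 2.32-fold, and NRF2 targets (10 of 17 rose and 3 fell, median 0.66, adjusted p 0.0335, adjusted p = 0.802 with an estimated correlation) had the cystine transporter Slc7a11 up 7.81-fold, Me1 5.69-fold and Gsr 3.78-fold. With the stricter filter the adjusted p was 0.2 for the cell cycle and 0.2 for NRF2 targets, with larger medians of 0.39 and 0.97. Other large rises were Tm4sf4 (271-fold), Il1rn (43.1-fold), Lama3 (39.4-fold), Cdh17 (34.6-fold), Il5ra (29.5-fold), Slc16a3 (27.4-fold) and Lamb3 (16.2-fold), and other large falls Fgfr1 (92.3-fold), Map2 (36.1-fold), Nrep (17.9-fold) and Thbs1 (10.04-fold). The unfolded protein response (11 higher and 1 lower of 20, median 0.24, adjusted p 0.0511) and dissociation genes (10 higher and 0 lower of 19, median 0.37, adjusted p 0.0511) stood just above 0.05. The lists passed 0.05 without 2nd relapse KP replicate 1 (0.0395) and without Parental KP replicate 3 (0.0203), and both with all libraries under median centring (0.0391 and 0.0293), array weights and a fit of these 2 groups only. NF-kB targets (12 higher and 3 lower of 18, adjusted p 0.103), chemokines (6 higher and 2 lower of 12, adjusted p 0.606), inhibitory ligands (6 higher and 3 lower of 13, 7 and 3 adjusted over the list alone, adjusted p 0.794), sensors (5 higher and 3 lower of 11, adjusted p 0.859), MYC targets (15 higher and 4 lower of 25, adjusted p 0.103), MAPK output (8 higher and 5 lower of 20, adjusted p 0.8) and p53 targets (10 higher and 5 lower of 18, adjusted p 0.275, Pmaip1 6.42-fold) were not called. For TGFB targets (9 higher and 7 lower of 20, adjusted p 0.92) the median was 0.08 while the test pointed down. The macrophage receptor Mrc1 rose 4.22-fold and Cd14 4.43-fold while Lyz2 fell 5.19-fold (macrophage list 2 higher and 2 lower of 4, adjusted p 0.794), pericyte gene Cspg4 rose 7.17-fold and Notch3 fell 8.88-fold (1 higher and 2 lower of 3, adjusted p 0.8). Cd53 fell 3.47-fold, Flt1 rose 1.48-fold, Krt14 and Cidec rose 9.04 and 54.6-fold, Xist fell by -0.61 and Bpgm (0.10) was not called. Satellite-like RNA stood at 145789 ± 20961 counts against 52843 ± 34917 in parental KP tumours.

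Late relapse KP tumours were higher in epithelial and cell-cycle genes than parental KP tumours (n = 3 per group), without a called interferon list. H2-K1 rose 4.04-fold to 3338 ± 306. Apob rose 76.4-fold to 14755 ± 2252, and the apolipoprotein gene Apoc2 stood at 2272 ± 418 against 1.17 ± 1.02 counts. Of 6365 called genes 3468 were higher and 2897 lower, with 246 higher and 56 lower by at least 1 log2 unit, which addressed a later stage of relapse. Quantile normalisation gave 2873 higher and 3557 lower, and median centring 3067 and 3418.

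Epithelial genes (14 of 19 rose and 1 fell, median 0.40, adjusted p 0.00469, adjusted p = 0.852 with an estimated correlation) had Hnf4a up 7.76-fold, Muc1 4.84-fold and Epcam 3.43-fold. Cell cycle genes (24 of 35 rose and 1 fell, median 0.28, adjusted p 0.00325, adjusted p = 0.852 with an estimated correlation) had Ube2c up 2.03-fold, with an adjusted p of 0.246 and a median of 0.29 under the stricter filter. Of the IFNG response genes 10 of 29 rose and 1 fell, median 0.15, adjusted p 0.171, with Ifi47 up 4.54-fold and Irf8 8.72-fold, and of the type I genes 9 of 20 rose and 2 fell, median 0.17, adjusted p 0.164. Oasl1 was up 3.24-fold. MHC class I and antigen processing (1 higher and 2 lower of 18, median 0.01 with a test pointing down, adjusted p 0.966) had Erap1 lower by -0.47, and H2-D1 (0.29), B2m (-0.13) and Tap1 (0.04) were not called. In the machinery 7 of 17 rose and 2 fell, adjusted p 0.547. Jak1 and Jak2 were up by 0.23 and 0.22, Ifngr1 and Ifngr2 up by 0.21 and 0.31 and Irf1 down by -0.22. The limma adjusted p became 0.147 for Ifngr1 without Late relapse KP replicate 3, 0.058 for Ifngr2 without its replicate 2 and 0.0519 for Irf1 without Parental KP replicate 2. MHC class II (2 higher and 0 lower of 3, adjusted p 0.59), inhibitory ligands (6 higher and 3 lower of 13, adjusted p 0.744, Lgals9 5.51-fold), chemokines (6 higher and 1 lower of 12, adjusted p 0.164, Cxcl5 6.02-fold), NF-kB targets (9 higher and 2 lower of 18, adjusted p 0.164) and sensors (4 higher and 0 lower of 11, adjusted p 0.444, Aim2 3.23-fold) were not called.

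Large single rises in late relapse KP were Cdhr2 (3192 ± 555 against 4.34 ± 2.67), Lgals2 (95.3-fold), Crisp1 (75.5-fold), Bmp7 (30.7-fold), Slc16a3 (26.6-fold) and Cdh17 (23.3-fold), and large falls Bgn (726 ± 669, 20.2-fold), Piezo2 (24.2-fold), Itpr2 (7.21-fold), Arntl2 (5.52-fold), Nrep (4.03-fold), Ppfibp1 (3.82-fold), Vcan (3.30-fold) and Col4a1 (3.08-fold). TGFB targets (11 higher and 6 lower of 20, adjusted p 0.444) had Ltbp2 up 7.29-fold, and mesenchymal genes (5 higher and 9 lower of 28, median -0.07, mean 0.08, adjusted p 0.448) had Spp1 up 2.81-fold. NRF2 targets (8 higher and 3 lower of 17, 10 and 4 adjusted over the list alone, adjusted p 0.166, Slc7a11 8.13-fold), hypoxia genes (12 higher and 5 lower of 24, adjusted p 0.171, Ero1l 2.25-fold) and MYC targets (4 higher and 12 lower of 25, adjusted p 0.129, 0.0129 without Late relapse KP replicate 1) were not called. Oxidative phosphorylation (11 higher and 5 lower of 27, 12 and 5 adjusted over the list alone, adjusted p 0.413), MAPK output (8 higher and 5 lower of 20, adjusted p 0.522, Spry1 11.7-fold), the unfolded protein response (10 higher and 1 lower of 20, adjusted p 0.164), dissociation genes (4 higher and 2 lower of 19, 2 and 2 adjusted over the list alone, median 0.04 with a test pointing down, adjusted p 0.966) and p53 targets (8 higher and 2 lower of 18, adjusted p 0.448, Pmaip1 4.86-fold) were not called. Macrophage genes (3 higher and 0 lower of 4, median 0.71, adjusted p 0.129) included Mrc1, up 3.19-fold, and Apoe, 3.87-fold, summing to 301 ± 56.8 against 110.3 ± 15.8 CPM. Fibroblast (1 higher and 1 lower of 13, 0 and 1 adjusted over the list alone, adjusted p 0.448) and pericyte (1 higher and 1 lower of 3, median 0.22, mean -0.07, adjusted p 0.966) lists were not called, Flt1 rose 1.66-fold, Xist fell by -1.15, and Cidec rose 18.5-fold. Satellite-like RNA stood at 172498 ± 55832 counts.

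2nd relapse KP tumours had lower fibroblast markers and higher hypoxia genes than 1st relapse tumours (n = 3 per group, preset correlation). Class I processing genes were lower in late than 1st relapse. Against 1st relapse, Col3a1 fell 36.8-fold, Sparc 42.4-fold and Col1a2 36.5-fold in 2nd relapse tumours, where 3835 genes were higher and 3132 lower (243 and 340 by at least 1 log2 unit). Late relapse tumours differed from 1st relapse by 2754 higher and 2626 lower genes (105 and 78; 1436 and 723 called with the satellite-like RNA as covariate, 1247 and 686 with the stricter filter), with Tap1 lower by -0.73. Fibroblast markers (13 of 13 fell and 0 rose, median -1.35, adjusted p 1.6e-05, adjusted p = 0.818 with an estimated correlation) and mesenchymal genes (20 of 28 fell and 4 rose, median -0.80, adjusted p 9.6e-05, adjusted p = 0.818 with an estimated correlation) were lower in 2nd relapse, and hypoxia genes (19 of 24 rose and 2 fell, median 0.59, adjusted p 4.7e-05, adjusted p = 0.818 with an estimated correlation) higher. Ndrg1 was up 5.83-fold. MYC targets (18 of 25 rose and 1 fell, 19 and 1 adjusted over the list alone, median 0.34, adjusted p 0.00375, adjusted p = 0.818 with an estimated correlation) were higher with Ncl up 2.11-fold, a call lost with quantile normalisation (0.179) and the stricter filter (0.0787, with a larger median of 0.49). IFNG response genes in 2nd against 1st relapse (5 higher and 14 lower of 29, 5 and 16 adjusted over the list alone, median -0.21, adjusted p 0.124) reached 0.0338 without 1st relapse KP replicate 2, H2-K1 was 2.07-fold higher, Jak2 2.01-fold higher and B2m lower by -0.65. Tm4sf4 (122-fold), Lgals2 (27.1-fold), Il5ra (20.3-fold) and the near-identical copy Prl2c3 (19.8-fold) rose most, and Tff2 stood at 5.16 ± 4.80 against 4405 ± 532.

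In late against 1st relapse the IFNG response (19 of 29 fell and 2 rose, 19 and 3 adjusted over the list alone, median -0.34, adjusted p 0.0035, adjusted p = 0.863 with an estimated correlation) and MHC class I genes (12 of 18 fell and 0 rose, 13 and 0 adjusted over the list alone, median -0.23, adjusted p 0.00298, adjusted p = 0.863 with an estimated correlation) were lower. Tapbp was down 1.91-fold and Psmb8 4.07-fold, and H2-K1 was not called (0.03). Epithelial genes (13 of 19 fell and 3 rose, median -0.48, adjusted p 0.00407, adjusted p = 0.863 with an estimated correlation) and fibroblast markers (12 of 13 fell and 0 rose, median -0.78, adjusted p 8.3e-04, adjusted p = 0.863 with an estimated correlation) were also lower, with Epcam down 2.84-fold, and hypoxia genes (13 of 24 rose and 4 fell, median 0.37, adjusted p 8.3e-04, adjusted p = 0.863 with an estimated correlation) higher. Ero1l was up 3.10-fold. Crisp1 (41.9-fold), Pdyn (23.5-fold), Rnu1b1 (15.6-fold) and Il5ra (11.5-fold) rose most, and Smoc2 (9.71-fold), Atad2 (4.75-fold), Col4a5 (4.32-fold) and Dmbt1 (3.12-fold) fell most. The stricter filter ended the IFNG (0.703), MHC class I (0.106) and epithelial (0.145) calls, as did the satellite-like RNA as covariate (0.117, 0.0536 and 0.128). Without Late relapse KP replicate 3 the cell cycle (0.148) and ligand (0.0987) lists reached 0.0154 and 0.031.

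**Figure D3:**
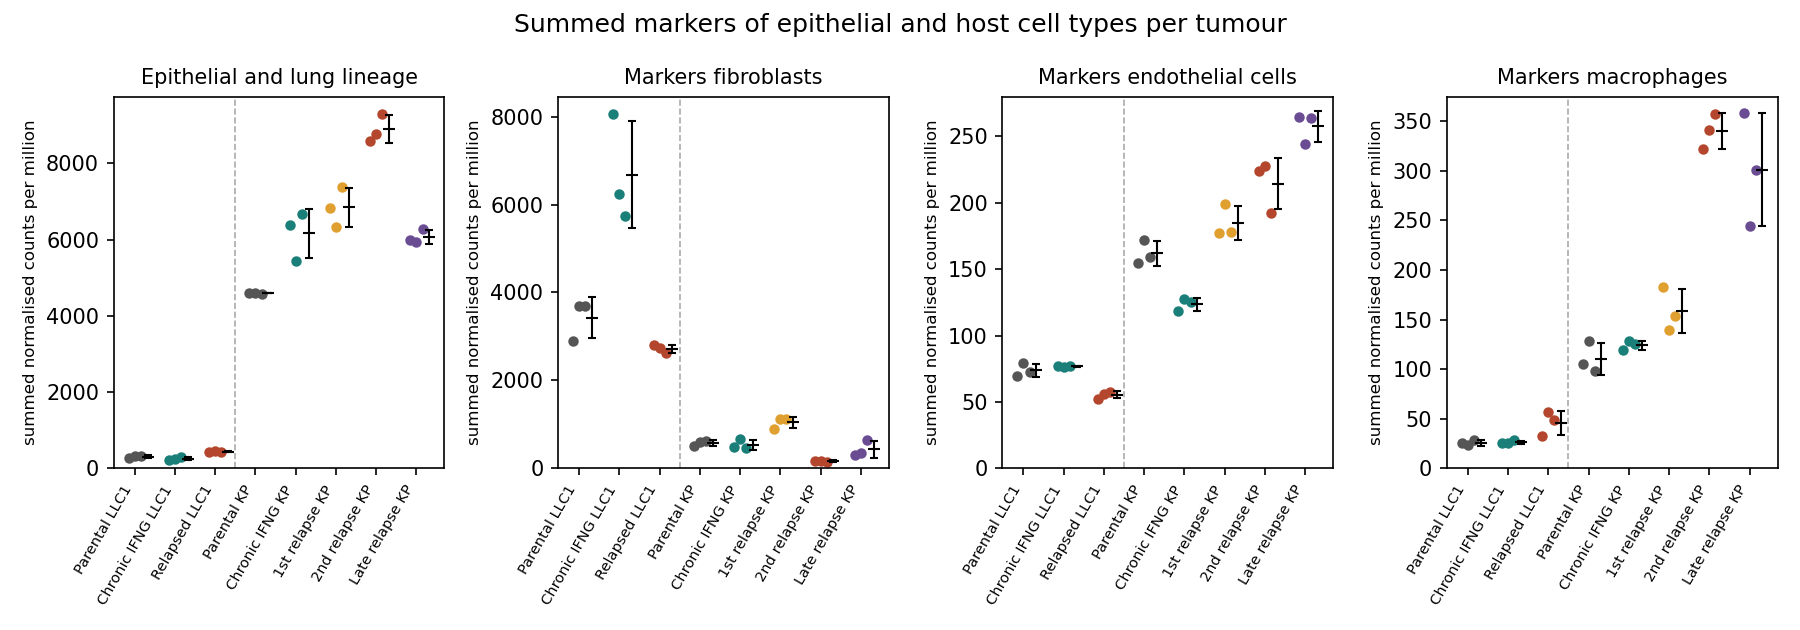
Summed normalised counts (CPM) of the epithelial, fibroblast, endothelial and macrophage lists in every tumour, with mean ± SD per group.

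Neighbouring genes moved together in many regions. Among overlapping windows of 25 genes, 22 lay below and 3 above every one of 1000 shuffled gene orders in 1st relapse KP, 109 below and 123 above in 2nd relapse, 196 below in late relapse and 0 in chronic IFNG KP. In LLC1 84 lay below in chronic IFNG tumours, and 85 below and 281 above in relapsed tumours. Shuffled orders were read only at spaced windows, so these counts may be somewhat high. The most extreme KP median, 0.87, was at chr15:77403789-79136900 in 2nd relapse, and regions on chromosomes 3, 8, 13, 17, 18 and X were lower in 1 or more relapse groups. On chromosome 15 (chr15:55307750-60853778) 13 of 25 genes were higher and 5 lower in 1st relapse, with a median log2 difference of 0.62, and 23 were higher and 1 lower in 2nd relapse (0.57). On distal chromosome 6 (chr6:142350342-147264183), 16 of 25 were lower and 2 higher in 1st relapse (-0.40), 17 and 7 in 2nd relapse (-0.46) and 14 and 2 in late relapse (-0.30).

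**Figure D4:**
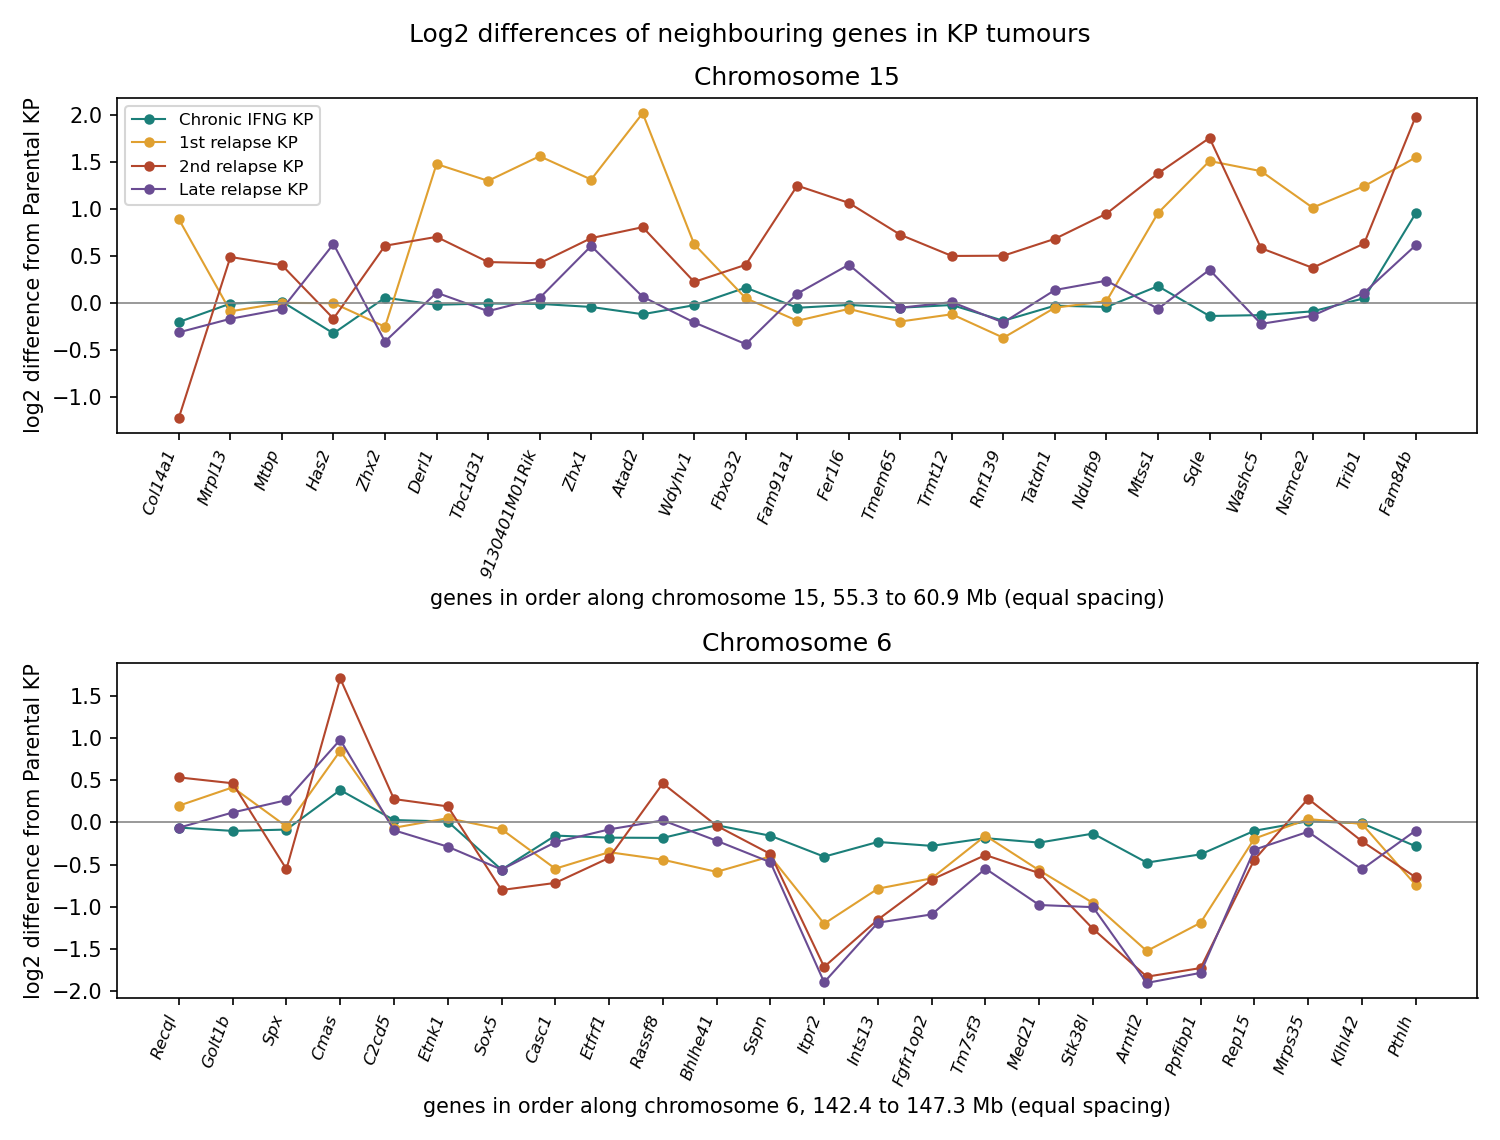
Log2 difference from parental KP of neighbouring genes in 2 blocks, on chromosomes 15 and 6, in the other 4 KP groups. One gene of the chromosome 6 block is not drawn.

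Interferon genes below the expression filter were low in KP. Cd274 stood at 34.9 ± 3.40 counts in parental, 28.7 ± 3.51 in chronic IFNG, 49.7 ± 7.27 in 1st, 65.7 ± 1.06 in 2nd and 82.3 ± 3.92 in late relapse tumours. Nlrc5 stood at 56.0 ± 40.1, 42.9 ± 16.9, 140.2 ± 73.8, 57.0 ± 25.6 and 67.2 ± 43.6 counts in the same order, Socs1 between 43.5 ± 5.24 and 69.9 ± 11.8, and the class II transactivator Ciita between 14.2 ± 10.3 and 49.4 ± 24.9. Cxcl9 reached 88.7 ± 48.0 counts in 1st relapse KP tumours and 152 ± 165 in chronic IFNG LLC1 tumours, against 39.6 ± 22.7 in parental and 15.1 ± 12.1 in relapsed LLC1 tumours. The leukocyte gene Ptprc, which encodes the CD45 used for sorting, stood at 27.1 ± 20.7, 16.6 ± 8.59 and 44.5 ± 24.9 in LLC1. In KP it stood at 104 ± 99.6 in parental, 64.1 ± 2.51 in chronic IFNG, 51.6 ± 34.4 in 1st, 28.4 ± 13.7 in 2nd and 38.1 ± 10.4 in late relapse tumours.

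The differences of chronic IFNG from parental KP were shared more with 1st than with 2nd or late relapse. For 1st relapse the log2 differences correlated at r = 0.81, with 1266 genes higher in both against 364 expected, 784 lower in both against 257 expected and 33 opposite. The correlation with chronic IFNG KP was 0.46 for 2nd and 0.52 for late relapse, and 0.14 between chronic IFNG and relapsed LLC1 with 323 genes higher in both, 530 lower in both and 572 opposite. Noise in the shared parental tumours alone gave r = 0.50 and a covariance of 0.003 in simulation, against measured covariances of chronic IFNG of 0.083, 0.064 and 0.052 with 1st, 2nd and late relapse KP and 0.011 with relapsed LLC1. 3 controls could not be split, so part of each excess may come from the shared controls. Across lines chronic IFNG differences correlated at r = 0.09 over 9822 genes. Of these 115 rose in both against 73.7 expected, 207 fell against 139 and 220 were opposite. Fisher exact p (7.7e-07 and 4.6e-10) assumes independent genes. Relapsed LLC1 correlated at 0.09 with 1st, -0.03 with 2nd and -0.05 with late relapse KP.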

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

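Comparisons between lines were not tested, and those between KP relapse groups were planned before the results were seen. Between lines, a list entered where all tumours of a group lay on 1 side of its parental mean and the other group's opposite. For relapsed LLC1 against the 9 KP relapse tumours the list means from parental were -0.077 against 0.30 for the IFNG response, -0.22 against 0.35 for type I interferon genes, -1.05 against 0.33 for chemokines, -0.16 against 0.21 for nucleic acid sensors, -0.16 against 0.44 for NRF2 targets and -0.63 against 0.17 for p53 targets. For chronic IFNG, LLC1 against KP, they were -0.16 against 0.75 for epithelial genes, -0.38 against 0.09 for hypoxia genes and -0.21 against 0.31 for NRF2 targets. The lines were normalised apart, and several lists covered different genes. Within KP, a list entered where the difference and 1 or both groups against parental were called and group medians had opposite signs. Hypoxia genes differed by 0.59 between 2nd and 1st relapse (camera adjusted p 4.7e-05, 0.818 with an estimated correlation) and by 0.37 between late and 1st relapse (8.3e-04, 0.863). Fibroblast markers differed by -1.35 (1.6e-05, 0.818) and -0.78 (8.3e-04, 0.863).

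For the splits below, regrouping was planned before the results were seen. The 6 tumours of each comparison can be split in 10 ways, so no share under 0.05 was possible. The real grouping called the most genes in all 9 comparisons (1 of 10 each time), and the highest count under another split was 1. In absolute value the real IFNG response median was the largest (1 of 10) in chronic IFNG LLC1 (0.49, next 0.40), relapsed LLC1 (0.14, next 0.10), relapsed against chronic LLC1 (0.48, next 0.43), 1st relapse (0.53, next 0.32), 2nd relapse (0.27, next 0.21) and late against 1st relapse (0.34, next 0.24). Counting the real grouping, 2 of 10 splits reached the real absolute median for chronic IFNG KP (0.20, highest other 0.20) and late relapse (0.15, highest other 0.19) and 3 of 10 for 2nd against 1st relapse (0.21, highest other 0.23).

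For 2 of several blocks of neighbouring genes in KP, the shuffles of gene order were chosen only after the blocks were seen. At chr15:55307750-60853778 the 25 genes had a median of 0.62 in 1st relapse, above the highest of 1000 shuffled orders (0.43) and of 10000 sets matched on GC and expression (0.18), which excludes both as the whole cause. At chr6:142350342-147264183 the median was -0.40 in 1st relapse, past the most extreme shuffled (-0.29) and matched (-0.20) values. The values are consistent with a copy-number change, which RNA alone cannot test and which was not tested.

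For satellite-like RNA at chr9:3000922-3038316, the test of copies and the correlations with silent genes were chosen only after the result was seen. Summed over 9 genes it fell to a ratio of 0.0205 in relapsed LLC1, so a different split of reads between copies is excluded. The ratio of 6037 silent genes was 0.505 ± 0.113, which leaves less DNA in these libraries undecided. Within groups both gene sets deviated together (r = 0.971 in LLC1 and 0.75 in KP), except in 2nd and late relapse KP. In 2nd and late relapse KP silent genes stood at 1.197 ± 0.334 and 1.09 ± 0.372 times parental against 2.76 and 3.26 for satellite-like genes. Silent counts need not track DNA, which stayed undecided.

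For lower p53 targets in relapsed LLC1, the host cell and Trp53 tests were chosen only after the result was seen. Under other scalings the median closest to 0 was -0.47, summed endothelial, pericyte, macrophage and leukocyte markers stood at 1.06 ± 0.147 times parental, and Trp53 RNA at 0.822 ± 0.034 against a target ratio of 0.605. Host lists moved apart, with pericytes at 34.2 ± 3.14 against 21.7 ± 1.36 CPM, endothelium at 55.4 ± 2.67 against 73.7 ± 5.04 and skin, muscle and fat at 3.35 ± 0.313 against 9.26 ± 1.72. Scaling or fewer of the summed host cells was not the whole cause. Targets need not track Trp53 RNA, so it stayed open. Fibroblasts, loss of 1 host type and a difference fixed in the relapsed line were not tested.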

How the results depend on the processing

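The satellite covariate and the back-calculated counts were chosen only after the results were seen. In the order chronic IFNG, relapsed, relapsed against chronic LLC1, then chronic IFNG, 1st, 2nd, late relapse, 2nd against 1st and late against 1st KP, the stricter filter tested fewer genes and called 1210, 1776, 1907, 972, 2001, 2515, 2197, 2452 and 1933 genes. A threshold of 1 log2 unit left 47, 150, 222, 131, 394, 753, 302, 583 and 183. With the replicate number as a block the counts were 2278, 4641, 5369, 2383, 5604, 7279, 6270, 6890 and 5272. The block moved no count past 1.5 times and no IFNG response call, dissociation genes in relapsed against chronic LLC1 (0.0473) and, with the unfolded protein response, in 2nd relapse (0.0313 each) gained a call, MYC targets in relapsed LLC1 lost it (0.0502), and 7 named genes gained and 10 lost a call. The numbers did not pair the libraries, since 0 of 9 LLC1 and 8 of 30 KP same-number pairs correlated above 0.1, and 0 of 9 and 6 of 15 libraries correlated best with their own number. Leaving out 1 library gave 1554 to 2748 called genes in chronic IFNG LLC1 and 1583 to 2583 in chronic IFNG KP. It moved the IFNG response median between 0.23 and 0.38 in 2nd relapse (adjusted p 0.0408 without 2nd relapse KP replicate 3) and between -0.37 and -0.14 in 2nd against 1st relapse (0.0338 without 1st relapse KP replicate 2). With an estimated correlation the IFNG response medians of 0.49, -0.48, 0.20, 0.53 and -0.34 lost their calls (adjusted p 0.36, 0.379, 0.672, 0.524 and 0.863). The stricter filter gave medians of 0.20 in chronic IFNG KP (0.577), 0.34 in 1st relapse (0.366) and -0.21 in late against 1st relapse (0.703). Without a filter medians of 0.12 in 2nd relapse (0.0207), 0.0367 in late relapse (0.035) and -0.17 in 2nd against 1st relapse (1.3e-04) gained calls. Of 213 list tests 68 were called, 2 with an estimated correlation, and 124 with fry. Without a filter more lists had enough members to be tested, and 126 were called. With the satellite covariate 1263 genes were called in relapsed LLC1, 2312 in relapsed against chronic LLC1 and 2159 in late against 1st relapse. Over all comparisons 159 named pairs lost and 10 gained a call with it. In relapsed LLC1 it turned the medians of the IFNG response to 0.37, of type I genes to 0.33 and of MYC targets to 0.0407. It turned Irf1 to 0.0492, Cd274 to 0.0777, Cxcl10 to 0.31, Iigp1 to 0.26, Ifit3 to 0.21, Ifit3b to 0.12 and Herpud1 to -0.0933, and the rise of Tgfb3 Relapsed LLC1 against Parental LLC1 to -0.0405. In relapsed against chronic LLC1 it moved the IFNG response median to -0.16 (0.463) and turned MHC class I to 0.10, hypoxia to 0.0344, B2m to 0.72, Tap1 to 0.095 and Usp18 to 0.0287. In late against 1st relapse, where satellite levels did not overlap, the IFNG response median was -0.20 (0.117). Quantile normalisation turned Cspg4 in 1st relapse to -0.058. Under the stricter filter the correlation of relapsed LLC1 was 0.17 with 1st, -0.0934 with 2nd and -0.14 with late relapse KP. Of 1012 named pairs of gene and comparison, 893 were called and 80 lost the call without some library. The cause was not tested.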

Other observations

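The shuffles of gene order were chosen only after the blocks were seen. In the chromosome 15 block of 1st relapse KP, Atad2 stood at 7954 ± 406 against 1571 ± 173 counts in parental tumours, Derl1 at 5732 ± 238 against 1721 ± 21.5 and Sqle at 6447 ± 343 against 1922 ± 140. Genes from Fbxo32 to Ndufb9 lay between them with log2 differences from -0.37 (Rnf139) to 0.05 (Fbxo32). In 2nd relapse the block median was 0.57, with 23 of 25 genes higher, above the highest shuffled order (0.54), and in late relapse and chronic IFNG it was -0.01 and -0.02. In the chromosome 6 block Itpr2 stood at 2482 ± 156 counts in parental, 807 ± 37.5 in 1st, 440 ± 47.0 in 2nd and 344 ± 64.8 in late relapse tumours. The block medians were -0.464 in 2nd relapse and -0.305 in late relapse, below the lowest shuffled orders of -0.453 and -0.298, and -0.15 in chronic IFNG.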
